A study of Mus musculus with 52 samples.

How the data were processed

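The series holds 52 RNA sequencing libraries from mouse embryonic stem cells that were differentiated as embryoid bodies in serum-free medium. Embryoid bodies were dispersed on day 2, cultured for 2 days with 100 ng/mL of Activin A or without it, and harvested on day 4, per the labels' protocols. Activin A is a ligand of the TGF beta family that signals through the same receptors as Nodal. Poly(A) mRNA was purified on oligo(dT) beads and made into libraries by unamplified standard RNA-seq from 50 ng, or by 3 amplification methods from 1 ng, 100 pg, 50 pg and 25 pg, per the labels. Smart-seq amplifies full-length cDNA by template switching and PCR, DP-seq amplifies cDNA with a designed set of short primers, and CEL-seq amplifies by in vitro transcription and reads the 3' ends of transcripts. Each of the 26 combinations of method, input and treatment has 2 libraries, which the labels call technical replicates. P-values of single genes therefore measure only the spread between technical replicates, and no p-value here measures that between cultures. Those of gene lists also rest on the spread between genes. Permutation tests use 8 groups per method that repeat the same 2 conditions and are not independent cultures.

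The authors deposited a table of unique read counts per RefSeq transcript for each library, per the file headers. In 36 tables all values were whole counts. In the other 16 tables, 21 values lay up to 0.00333 from a whole number; these deposited values were treated as estimated counts and rounded. The aligner, the mismatch limits, the strand setting and the genome build are not given in the sources used here. Reads that map to more than 1 transcript are absent from a unique count, so genes with near-identical copies, such as ribosomal protein genes and Tdgf1 with their processed pseudogenes, are uncertain, as are overlapping and antisense genes. Total unique reads ranged from 8516455 to 12254872 per standard library, from 9749623 to 15597932 in Smart-seq, from 4056243 to 13758365 in DP-seq and from 2255515 to 11061474 in CEL-seq. The values count reads, which amplification copies from fewer molecules, so intervals and floors cover counting error only.

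Of the 26566 transcript identifiers, 25857 were named from a RefSeq gene table (assembly GRCm38.p6, used for names only) and 150 from the GENCODE M21 transcript table. The remaining 559 had no symbol and held at most 2.526% of a library's reads; they stayed in the fits and are not named. Counts of transcripts of the same gene were summed, which gave 21844 features. The 3080 genes with more than 1 transcript held 1.21% to 2.8% of a library's reads. Reads shared between transcripts of a gene are absent from a unique count, so the levels of these genes are uncertain as well. The tables held no mitochondrially encoded genes, so that class gave no value.

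Replicates were compared by a chi-square test over genes with 10 or more reads in the pair. The 2 standard Activin A libraries differed by no more than read sampling (chi-square per degree of freedom 0.998, p = 0.57 over 13077 genes), whereas the standard control pair gave 1.17 and the amplified pairs 3.65 to 313. The standard Activin A pair was therefore summed and counted as 1 sample. That choice was made after the counts were seen and departs from the design of 2 against 2 libraries; keeping the pair as 2 libraries was added as an alternative, as was testing transcripts without summing them per gene. The standard comparison then has 1 Activin A sample, 2 control libraries and 1 residual degree of freedom, so the Activin A sample is assumed to vary like the control libraries and the spread is that of 2 technical replicates.

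Differential expression was tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on counts, with TMM normalization, genes kept by filterByExpr and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. Standard RNA-seq and each of the 12 combinations of amplification method and input were fitted separately, and each method also over its 16 libraries with input as a factor. The difference of the Activin A response between standard RNA-seq and each method at 1 ng, and between 25 pg and 1 ng within each method, was tested as an interaction. Genes with an unadjusted p under 0.05 are counted beside some results. A share of about 0.05 of the tested genes would reach it with no response, so these counts are not calls. Standard errors of log2 fold changes are Wald errors from the fitted weights and the moderated quasi-dispersion; on simulated counts 93.5% to 95.7% of the errors lay within 2 standard errors. A gene with 0 reads on one side has no standard error and is given as a lower bound against a floor of 3 reads over the group; a gene with 1 to 3 reads is given with the 95% counting interval of its ratio. CPM values of named genes were computed from the deposited counts with TMM-normalized library totals within each method. CPM values in replicate noise, agreement of levels, transcript length and shares of the other condition's level used library totals without TMM.

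Gene lists were fixed before the data were examined: 18 lists of lineage, signalling and metabolic genes and cell types the cultures could hold, plus ribosomal protein genes. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, adjusted over the 19 lists of each fit, and again with the correlation estimated. The genes named in the text were also chosen by a rule fixed before the data were examined: in standard RNA-seq the 12 higher and 12 lower genes with the largest change among called genes with 10 CPM or more and no overlap between groups; up to 4 members of each list with the smallest adjusted p; for each difference of responses the 4 genes with the smallest p; for losses at 25 pg the 4 genes called in standard RNA-seq with the highest level and 0 reads in a method; and for each method the 4 genes with the smallest p that were not called in standard RNA-seq at 10 CPM or more there. Some genes that this rule names are not reported here.

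Genes detected and replicate noise were computed per group after thinning each library to 2255515 reads. Replicate noise is the median absolute log2 ratio of CPM + 1 between the replicates over genes with 10 CPM or more in standard RNA-seq. Agreement of levels is Spearman's rho across genes with 1 CPM or more, on group means without thinning. Relations to input were tested by exact permutation of pairings over 8 groups per method, and methods were compared by a two-sided exact sign-flip permutation test over 8 matched groups, where the smallest p is 2 of 256; both families of 9 were adjusted by Benjamini-Hochberg. Transcript lengths came from GENCODE M21 and covered 96.3% of genes.

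Alternatives fixed before the data were examined were DESeq2 (1.42.0), RLE size factors, no filter on low counts, the replicate number as a block, thinned libraries, a fold threshold of 2, leaving out each library, a shared fit over the inputs of a method, leaving out 25 pg, other minimum levels, pseudocounts and detection counts, and an estimated inter-gene correlation. A block in a fit with standard RNA-seq needs its Activin A pair as 2 libraries, so that alternative changes both choices there. The tests were checked on simulated counts in which 200 genes were changed by known folds. Far more genes were called in the data (10360 of 13481 in standard RNA-seq), so scaling and false calls were not checked at such a share. In that simulation of the standard comparison, 90 of 100 genes changed 2-fold and 94 of 100 changed 8-fold were recovered, with 11 false calls among 13481 genes. For Smart-seq at 1 ng the corresponding counts were 51 and 97 with 4 false calls, for Smart-seq at 25 pg 1 and 34 with 4, for DP-seq at 1 ng 75 and 97 with 12, for CEL-seq at 1 ng 10 and 79 with 9, and for CEL-seq at 25 pg 0 and 0 with 0. Tables and permutation tests were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.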

Results

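Libraries were prepared from mouse embryonic stem cells on day 4 of differentiation in serum-free medium, after 2 days with 100 ng/mL of Activin A or in control medium. The series asks how amplification method and amount of mRNA change the technical variation of RNA-seq, so the Activin A response in unamplified standard RNA-seq served as the reference. Standard RNA-seq used 50 ng of mRNA. Smart-seq, DP-seq and CEL-seq each used 1 ng, 100 pg, 50 pg and 25 pg. Each of the 26 groups held 2 technical replicates, and the 52 libraries held 2255515 to 15597932 unique reads. The 2 standard Activin A libraries differed by no more than read sampling and were counted as 1 sample, so standard RNA-seq compares 1 Activin A sample with 2 control libraries.

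In standard RNA-seq, genes of the primitive streak, of definitive endoderm and of the Nodal pathway rose with Activin A and neuroectoderm genes fell. All 12 primitive streak and mesendoderm genes were called higher. Lhx1 (NM_008498.2), a LIM homeobox transcription factor of the early mesendoderm, rose from 0.642 ± 0.168 CPM (SD, n = 2) to 514 CPM, a log2 fold change of 9.62 ± 0.37 (SE). T (Brachyury) rose from 10.2 ± 1.14 CPM (SD, n = 2) to 497 CPM, a log2 fold change of 5.60 ± 0.10 (SE), and the homeobox genes Mixl1 and Gsc changed by 6.44 ± 0.32 and 6.24 ± 0.39. Of 10 definitive endoderm genes tested, 8 rose, among them the transcription factors Sox17 (7.33 ± 0.38), Hhex (5.92 ± 0.20) and Foxa2 (3.48 ± 0.07) and the secreted antagonist Cer1 (7.81 ± 0.19). Of 15 genes of the Nodal and Activin pathway and its feedback, 12 rose and 1, the receptor gene Acvr2b, fell. The Nodal antagonist Lefty1 changed by 8.28 ± 0.65, the co-receptor genes Tdgf1 and Cfc1 by 8.78 ± 0.31 and 6.81 ± 0.35, and the Smad partner Foxh1 by 3.47 ± 0.09. Of 14 neuroectoderm genes tested, 12 fell and Zic2 rose (1.68 ± 0.04). The neural transcription factors Sox1, Pax6 and Sox3 had log2 fold changes of -7.52 ± 0.24, -7.71 ± 0.45 and -2.71 ± 0.08.

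The 4 lists passed camera (adjusted p = 4.24e-05 for primitive streak, 0.00244 for definitive endoderm, 0.000162 for the Nodal pathway and 0.000162 for neuroectoderm). None of these calls held when the inter-gene correlation was estimated from the 1 residual degree of freedom of this comparison (adjusted p = 0.697, 0.739, 0.697 and 0.697 with an estimated correlation). In standard RNA-seq the counts of called members adjusted over the list alone equalled those over all genes for each of the 19 lists.

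Glycolysis and hypoxia genes rose in 10 of 12 cases and fell in 1, the glucose transporter gene Slc2a1 (-0.99 ± 0.02). The glycolytic enzyme genes Pgk1 and Pkm changed by 1.39 ± 0.03 and 0.86 ± 0.02, and the hypoxia-inducible Bnip3 by 3.23 ± 0.08. Ribosomal protein genes rose in 64 of 78 cases and fell in 8, with a median log2 fold change of 0.50 (0.49 with RLE and 0.53 with DESeq2 scaling) and 1.15 ± 0.02 for Rpl23. Of 15 cholesterol synthesis genes, 13 fell and 2 rose, the rising ones being Fdft1 and Fdps. Insig1, a sterol-responsive regulator, had a log2 fold change of -1.34 ± 0.05 and Hmgcs1 -0.49 ± 0.02. The camera tests gave adjusted p = 0.000864 for glycolysis and hypoxia, 2.73e-05 for ribosomal proteins and 0.0145 for cholesterol synthesis, and each became adjusted p = 0.697 with an estimated correlation.

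The other lists did not pass camera. Among core and primed epiblast genes 7 rose and 4 fell (adjusted p = 0.286): Pou5f1, Fgf5 and Utf1 changed by 5.13 ± 0.10, 6.52 ± 0.16 and 5.64 ± 0.18, whereas the RNA-binding protein gene Lin28a changed by -1.12 ± 0.02. Of 7 naive pluripotency genes tested, 6 rose, with Nanog at 4.50 ± 0.26, and Tfcp2l1 fell, a call lost with DESeq2 (adjusted p = 0.101) and with thinned libraries (adjusted p = 0.0926); the list had adjusted p = 0.105. The epithelial to mesenchymal transition list divided into 6 higher and 6 lower genes (adjusted p = 0.684). The epithelial genes Cdh1, Epcam and Cldn6 rose by 5.02 ± 0.05, 5.51 ± 0.11 and 6.17 ± 0.13, and Zeb2, a repressor of Cdh1, had a log2 fold change of -3.15 ± 0.08. Paraxial mesoderm genes rose in 6 and fell in 3 of 9 cases (adjusted p = 0.657), with the Notch ligand Dll1 and the Notch modifier Lfng at -4.08 ± 0.14 and -4.10 ± 0.13 and Dll3 at 2.81 ± 0.15.

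Markers of other cell types that such cultures could hold did not move together. Haematovascular and lateral mesoderm genes rose in 5 and fell in 2 of 9 cases (adjusted p = 0.262), none of the 4 named members exceeding 5.86 CPM in the Activin A sample. Extraembryonic endoderm genes rose in 3 and fell in 5 of 9 cases (adjusted p = 0.684), with Lama1 at -4.67 ± 0.13 and Apoe at 1.35 ± 0.05. Trophoblast genes rose in 3 and fell in 1 of 6 cases (adjusted p = 0.286), with the keratin gene Krt7 rising from 0.691 ± 0.380 CPM (SD, n = 2) to 20.6 CPM. Fibroblast genes rose in 3 and fell in 3 of 8 cases (adjusted p = 0.676), with Col3a1 at 9.67 ± 0.516 CPM (SD, n = 2) in control and 0.178 CPM with Activin A.

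The 12 higher genes with the largest change included Lhx1, Tdgf1, Lefty1, Cer1, Sox17, Foxd3, Pga5, Tuba8, Cfap206, Cfc1 and Foxq1, with fitted folds from 111 for Foxq1 to 786 for Lhx1. Of these, Cfap206 did not pass in DESeq2 (adjusted p = 0.0822). The 12 lower genes were Wnt1, Hes3, Pax5, Fezf1, En1, Slitrk6, Pax2, Pdzph1, Nr2f1, Rn7sk, Dcc and Dbx1. Wnt1, a ligand gene of the midbrain and hindbrain boundary, had 124 ± 0.308 CPM (SD, n = 2) in control and no read with Activin A, which makes it at least 845-fold lower. Hes3, Pax5, Fezf1 and Slitrk6 also had no read there and were at least 598-fold, 411-fold, 297-fold and 176-fold lower. The homeobox gene En1 had 278 ± 0.936 CPM (SD, n = 2) in control and 1 read with Activin A, a ratio of 5680 with a 95% counting interval of 1020 to 224000. Pax2 had a ratio of 1220 (218 to 48100).

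In all, 10360 of 13481 genes were called in standard RNA-seq, 5261 higher and 5099 lower (edgeR), 7162 by DESeq2, and 4360 with a fold of 2 or more. The lone Activin A sample is assumed to vary like the control libraries; with the pair kept as 2 libraries 10172 genes were called. With libraries thinned to 2255515 reads, 5464 genes were called. The standard libraries also differed in RNAs that lack a poly(A) tail: the 28S ribosomal RNA gene Rn28s1 had 28100 ± 213 CPM (SD, n = 2) in control and 260 CPM with Activin A, and the small nuclear RNA Rn7sk had 63.6 ± 3.46 CPM and 0.138 CPM.

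**Figure D1:**
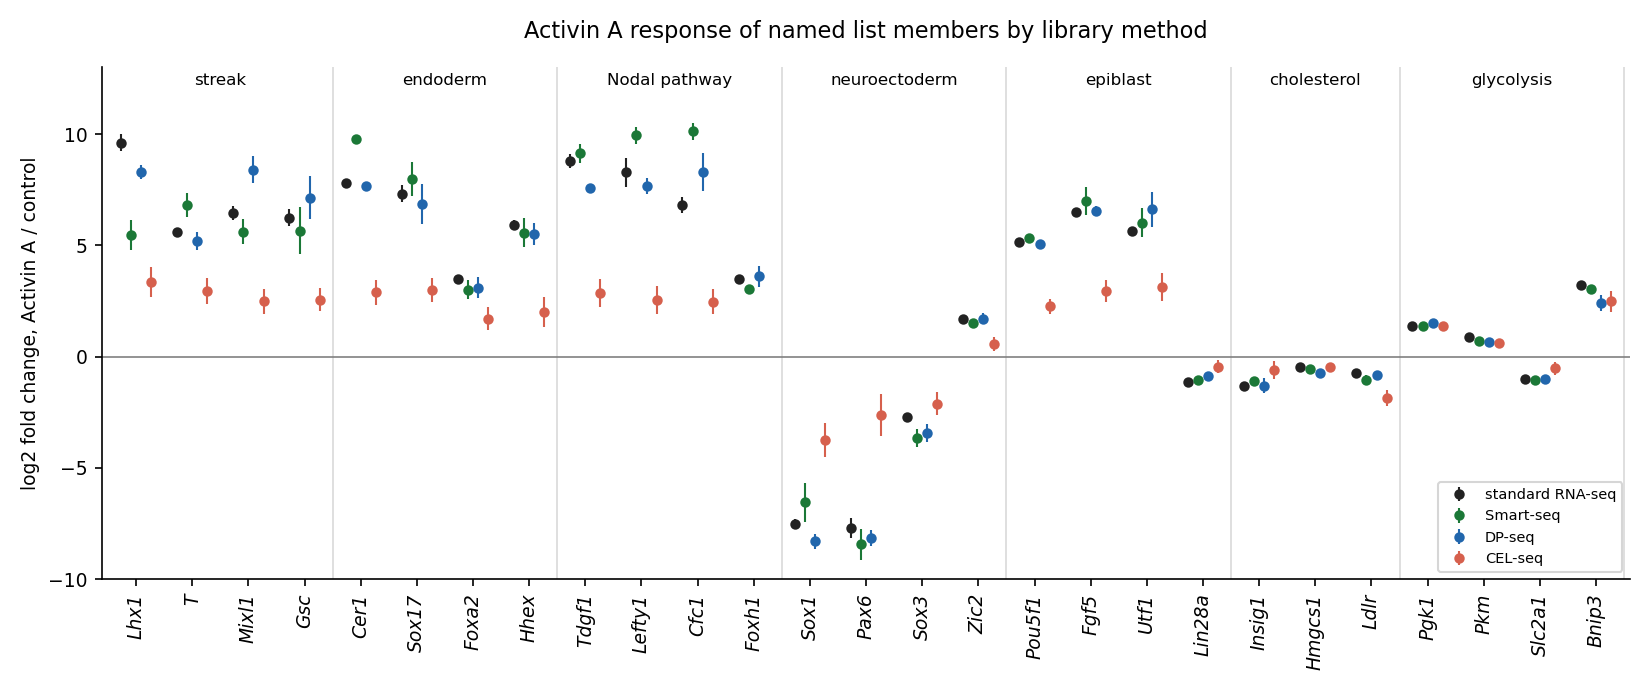
Log2 fold changes (Activin A over control, vertical axis) of named members of 7 gene lists in standard RNA-seq and in Smart-seq, DP-seq and CEL-seq over all inputs, with bars of 1 SE. Sox17 lies at 7.33 in standard RNA-seq, 7.99 in Smart-seq and 6.87 in DP-seq but at 3.0 in CEL-seq.

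Over all inputs, the amplified methods gave the same directions for the leading genes. Of the 12 higher genes named above, Smart-seq called 12, DP-seq 12 and CEL-seq 11 as higher, and of the 12 lower genes they called 12, 11 and 7 as lower; CEL-seq tested only 10 of the lower genes. The exceptions were Foxd3 in CEL-seq (3.06 ± 0.94, adjusted p = 0.0944), Rn7sk in DP-seq (-1.10 ± 1.21, adjusted p = 0.555) and Fezf1, Dcc and Dbx1 in CEL-seq (adjusted p = 0.177, 0.0788 and 0.0742). Sox17 changed by 7.99 ± 0.76 in Smart-seq, 6.87 ± 0.90 in DP-seq and 3.0 ± 0.55 in CEL-seq, and Pou5f1 by 5.34 ± 0.18, 5.08 ± 0.17 and 2.26 ± 0.33. Pgk1 changed by 1.38 ± 0.06, 1.5 ± 0.10 and 1.37 ± 0.20, whereas Lin28a had log2 fold changes of -1.05 ± 0.08, -0.85 ± 0.09 and -0.45 ± 0.28 (adjusted p = 0.342 in CEL-seq). Edge cases among weakly expressed genes went both ways. Kdr, a receptor gene of vascular precursors, changed by 0.75 ± 0.21 in standard RNA-seq (adjusted p = 0.181 in DESeq2), -4.01 ± 1.23 in Smart-seq (adjusted p = 0.0146) and 3.85 ± 1.04 in DP-seq (adjusted p = 0.0341), with at most 1.23 CPM in any Smart-seq group. Tbx20 changed by 1.59 ± 0.34 in standard RNA-seq, -2.89 ± 0.77 in Smart-seq (adjusted p = 0.0116) and -2.11 ± 0.58 in CEL-seq (adjusted p = 0.0499). It is among the genes with more than 1 transcript, so its counts leave out reads that its transcripts share.

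The same 4 lists moved in the same directions in all 3 methods. In Smart-seq 8 of 12 primitive streak genes rose (9 adjusted over the list alone), as did 7 of 11 definitive endoderm genes and 11 of 14 Nodal pathway genes, with Acvr2b lower; 9 of 13 neuroectoderm genes fell (10 adjusted over the list alone) and Zic2 rose, the other counts being equal adjusted over the list alone. These lists passed camera with adjusted p of 1.37e-06, 9.2e-07, 2.39e-08 and 0.000233, and with the correlation estimated (adjusted p = 0.00218, 0.00613, 0.00167 and 0.00613). In DP-seq 8 of 11 primitive streak, 7 of 10 definitive endoderm and 7 of 12 Nodal pathway genes rose and 8 of 14 neuroectoderm genes fell (adjusted p = 2.5e-08, 4.23e-07, 1.05e-07 and 3.57e-07; 0.00147, 0.00147, 0.00515 and 0.00147 with an estimated correlation). Adjusted over the list alone, the DP-seq counts were 8, 7, 8 and 8, with 1 Nodal pathway gene lower. In CEL-seq 5 of 7 primitive streak, 4 of 10 definitive endoderm and 7 of 11 Nodal pathway genes rose and 4 of 11 neuroectoderm genes fell, or 6, 6, 7 and 7 adjusted over the list alone, with 1 Nodal pathway gene lower. The CEL-seq lists passed camera at adjusted p of 2.49e-06, 7.29e-05, 3.25e-05 and 0.00105 but not with an estimated correlation (adjusted p = 0.09, 0.09, 0.134 and 0.112).

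Glycolysis and hypoxia genes rose in 10 of 12 cases in Smart-seq, 8 of 12 in DP-seq and 4 of 10 in CEL-seq (adjusted p = 3.79e-07, 0.000206 and 0.00167; 0.00571, 0.00515 and 0.09 with an estimated correlation). Slc2a1 fell in Smart-seq and DP-seq (-1.05 ± 0.11 and -1.02 ± 0.11). Cholesterol synthesis genes fell in 11 of 15 cases in Smart-seq, 6 of 14 in DP-seq, where Fdft1 rose, and 3 of 14 in CEL-seq (adjusted p = 0.000919, 0.00742 and 0.118; 0.0105, 0.0557 and 0.235 with an estimated correlation). Adjusted over the list alone, 11, 8 and 4 glycolysis and hypoxia genes were higher and 12, 6 and 3 cholesterol synthesis genes lower. Ribosomal protein genes rose in 70 of 80, 20 of 77 and 19 of 80 cases (adjusted p = 2.71e-13, 0.00564 and 7.32e-07; 0.294, 0.176 and 0.235 with an estimated correlation). Adjusted over the list alone, the higher ribosomal protein genes were 71, 20 and 30. Core and primed epiblast genes rose in 6, 5 and 4 cases and fell in 2, 3 and 1 (adjusted p = 0.0171, 0.017 and 0.0631; 0.0454, 0.0487 and 0.134 with an estimated correlation). Adjusted over the list alone, the epiblast counts were 6, 5 and 4 higher and 2, 3 and 2 lower. In DP-seq alone among the 4 methods, naive pluripotency genes (3 of 8 higher, 4 adjusted over the list alone, adjusted p = 0.00296, and 0.018 with an estimated correlation) and trophoblast genes (3 of 5 higher, 3 adjusted over the list alone, adjusted p = 0.0228, and 0.0557 with an estimated correlation) passed; whether these lists differ between methods was not tested.

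Over all inputs Smart-seq called 4384 genes (2047 higher, 2337 lower), DP-seq 2628 (1409 higher, 1219 lower) and CEL-seq 719 (289 higher, 430 lower). DESeq2 called 1853 genes in CEL-seq, and edgeR called 1546 there without the 25 pg libraries. In CEL-seq, replicate 2 had more genes detected after thinning than replicate 1 in 8 of 8 groups, against 4 of 8 in Smart-seq and 3 of 8 in DP-seq. With the replicate number as a block, edgeR called 242 CEL-seq genes over all inputs, 1 at 1 ng and 0 at 25 pg. At 25 pg, 147 of 6217 tested genes had an unadjusted p under 0.05, fewer than would reach it with no response. DESeq2 without the block called 420 there.

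The dilution series asked how much of the response each input retained. At 1 ng, Smart-seq called 12 of the 12 leading higher genes and 10 of the 12 leading lower genes, DP-seq called 12 and 11, and CEL-seq called 1 and 5. At 100 pg the counts were 9 and 10 in Smart-seq and 11 and 9 in DP-seq, at 50 pg 8 and 7 and 8 and 6, and at 25 pg 4 and 2 and 3 and 2. In CEL-seq edgeR called none of these 24 genes at 100, 50 or 25 pg, although 17, 19 and 2 of them had an unadjusted p under 0.05, and DESeq2 called 8 higher and 8 lower at 100 pg, 12 and 7 at 50 pg and 0 and 2 at 25 pg. Every leading gene that was tested in one of these 12 fits had the sign it had in standard RNA-seq.

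Smart-seq called 5222 genes at 1 ng (2455 higher, 2767 lower), 1809 at 100 pg (1013 and 796), 739 at 50 pg (477 and 262) and 71 at 25 pg (53 and 18). DP-seq called 5565 (2799 and 2766), 1006 (495 and 511), 555 (285 and 270) and 61 (25 and 36). The biological coefficient of variation fitted to these libraries rose from 0.139 to 0.837 in Smart-seq and from 0.105 to 0.936 in DP-seq between 1 ng and 25 pg, against 0.0119 in standard RNA-seq. CEL-seq called 197 genes at 1 ng (66 higher, 131 lower), 0 at 100 pg and at 50 pg by edgeR, and 48 at 25 pg, which were all lower. At 100 and 50 pg, 2091 of 9397 and 2903 of 8550 tested CEL-seq genes had an unadjusted p under 0.05, and DESeq2 called 1123 and 2162.

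These counts depended on the tool and on single libraries. DESeq2 called 2237 and 1317 genes in Smart-seq and 1784 and 758 in DP-seq at 50 and 25 pg, and 690 and 420 in CEL-seq at 1 ng and 25 pg; without a filter on low counts edgeR called 1522 genes in CEL-seq at 1 ng. With a spread shared over the inputs of a method, the order over inputs was turned around in Smart-seq and DP-seq. The shared biological coefficient of variation, 0.653 and 0.685, lay above the values fitted at 1 ng alone and below those at 25 pg. The counts were 543, 1048, 1863 and 2189 genes from 1 ng to 25 pg in Smart-seq, and 302, 393 and 1796 at 1 ng, 100 pg and 25 pg in DP-seq. In CEL-seq this fit gave 0 genes at 1 ng and 25 pg by edgeR. Of 10755 tested genes, 210 and 2698 had an unadjusted p under 0.05, and 210 is fewer than would reach it with no response. In Smart-seq, leaving out Activin A replicate 1 or 2 left 323 or 280 genes at 100 pg, 11 or 10 at 50 pg and 0 at 25 pg, and leaving out control replicate 1 or 2 gave 1067 or 1017 at 100 pg and 1924 or 1791 at 50 pg. Without control replicate 1, Smart-seq called 44 genes at 25 pg. In DP-seq, leaving out Activin A replicate 1 or 2 gave 3581 or 3644 genes at 1 ng, 234 or 222 at 50 pg and 179 or 141 at 25 pg; without control replicate 1 there were 1660 at 100 pg, without control replicate 1 or 2 there were 2236 or 2031 at 50 pg, and without control replicate 2 there were 111 at 25 pg. In CEL-seq at 1 ng the count was 0 without control replicate 1, 607 without control replicate 2, 417 without Activin A replicate 1 and 1417 without Activin A replicate 2. It reached 951, 12 and 700 at 100 pg without control replicate 2, Activin A replicate 1 and Activin A replicate 2, and 186, 851 and 2952 at 50 pg without control replicate 1, control replicate 2 and Activin A replicate 2. At 25 pg it was 3, 87, 0 and 9 without control replicates 1 and 2 and Activin A replicates 1 and 2.

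**Figure D2:**
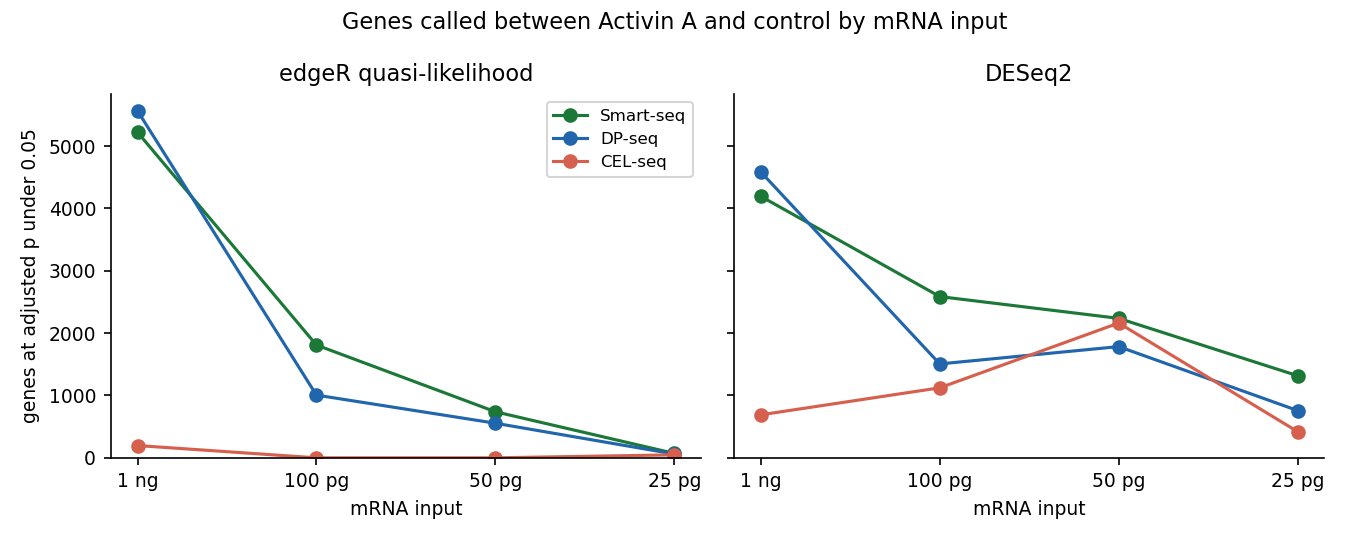
Number of genes called between Activin A and control (vertical axis) at each mRNA input (horizontal axis) in Smart-seq, DP-seq and CEL-seq, by edgeR on the left and DESeq2 on the right. In edgeR the counts fall from 5222 to 71 in Smart-seq and from 5565 to 61 in DP-seq, and in DESeq2 from 4194 to 1317 and from 4585 to 758.

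Of the 10360 genes called in standard RNA-seq, Smart-seq called 43.7% in the same direction at 1 ng (95% exact binomial interval over genes 42.7 to 44.6), 15.4% at 100 pg, 6.34% at 50 pg and 0.685% at 25 pg (0.536 to 0.864). DP-seq called 48.2% (47.3 to 49.2), 9.46%, 4.95% and 0.589% (0.451 to 0.756). CEL-seq called 1.77% at 1 ng and 0.299% at 25 pg, and 0% at 100 and 50 pg by edgeR, where DESeq2 called 745 and 1117 of its own 7162 standard calls in the same direction. From 100 to 25 pg DESeq2 called 29.4%, 23.1% and 14.5% of these 7162 in Smart-seq and 18.8%, 19.6% and 7.89% in DP-seq. At 1 ng 4526 of the Smart-seq calls and 4997 of the DP-seq calls had the standard direction, where independent lists would share 1990 and 2220, and 96 and 143 had the opposite direction. Opposite calls numbered 34 of 1809 at 100 pg, 54 of 739 at 50 pg and 0 of 71 at 25 pg in Smart-seq, 3 of 1006, 21 of 555 and 0 of 61 in DP-seq, and 4 of 197 at 1 ng and 9 of 48 at 25 pg in CEL-seq. Fold changes were compared across genes with 10 CPM or more in standard RNA-seq, which are not independent replicates. Pearson's r was 0.92, 0.808, 0.728 and 0.665 from 1 ng to 25 pg in Smart-seq, 0.932, 0.806, 0.737 and 0.591 in DP-seq and 0.738, 0.517, 0.405 and 0.334 in CEL-seq. The slope on the standard log2 fold changes at 1 ng was 0.874 in Smart-seq, 0.865 in DP-seq and 0.456 in CEL-seq.

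Differences of the Activin A response between each method at 1 ng and standard RNA-seq were tested as interactions. Rn28s1 had the smallest p in all 3 tests: its response lay above that in standard RNA-seq by a log2 of 5.23 ± 0.16 in Smart-seq (adjusted p = 1.71e-07), 6.03 ± 0.07 in DP-seq (adjusted p = 6.15e-13) and 5.78 ± 0.28 in CEL-seq (adjusted p = 0.00271). Scube1, a secreted and cell-surface protein gene, fell in standard RNA-seq (-6.39 ± 0.25) and differed by 5.66 ± 0.27 in Smart-seq and 5.65 ± 0.39 in CEL-seq (adjusted p = 1.11e-06 and 0.00722). The forkhead gene Foxq1 rose less in Smart-seq than in standard RNA-seq, with a difference of -4.72 ± 0.38. The adaptor protein gene Ap1s3 rose in standard RNA-seq (2.32 ± 0.10) and fell in Smart-seq at 1 ng (-0.86, adjusted p = 0.0133), a difference of -3.26 ± 0.27 (adjusted p = 0.000306 for both differences). In DP-seq the nuclear non-coding RNA Malat1 differed by 1.81 ± 0.09 (adjusted p = 3e-06), the ciliogenesis regulator Foxj1 by -3.27 ± 0.20 (adjusted p = 1.21e-05) and Rpl37 by -1.34 ± 0.09 (adjusted p = 1.71e-05). In CEL-seq En1, with 1 read in the standard Activin A sample, differed by 9.52 ± 1.36 (adjusted p = 0.00722) and Adam19 by -3.14 ± 0.26 (adjusted p = 0.00983).

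Smart-seq differed from standard RNA-seq in 146 genes, 35 above and 111 below it (84 genes with RLE scaling, 39 above and 45 below). DP-seq differed in 901 genes, 162 above and 739 below (605 with RLE scaling, 189 above and 416 below), and CEL-seq in 63 genes, 45 above and 18 below (343 by DESeq2). With the standard Activin A pair kept as 2 libraries the counts were 951 (217 above, 734 below), 1584 (734 and 850) and 469 (244 and 225), and without a filter on low counts 30, 361 and 12. With the pair kept as 2 libraries and the replicate number as a block as well, the counts were 1550, 1295 and 53. The 3 tests share the standard libraries and differ in their fitted spread, so their counts do not rank the methods by the size of the difference.

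Between 25 pg and 1 ng no gene was called for a different response by edgeR in any of the 3 methods. The biological coefficient of variation fitted in these tests was 0.637 in Smart-seq, 0.705 in DP-seq and 0.803 in CEL-seq. In simulated counts the response at 25 pg alone recovered 34 of 100 genes changed 8-fold in Smart-seq and 0 in CEL-seq. Power was therefore low, and the absence of calls does not show equal responses. An unadjusted p under 0.05 was reached by 1337 of 12393 tested genes in Smart-seq, 1361 of 11398 in DP-seq and 563 of 9668 in CEL-seq. DESeq2 called 531, 736 and 0.

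Among the 10360 genes called in standard RNA-seq, those with a symbol and without reads at the lowest input were counted. Called features without a symbol were not counted as lost but stay in the total of the shares. At 25 pg, 449 of them (4.33%) had no read in any of the 4 Smart-seq libraries, 1039 none in DP-seq and 3303 (31.9%) none in CEL-seq. At 1 ng of the same method 428, 964 and 2755 of these had reads and 21, 75 and 548 had none. Those with the highest standard level were Foxo3, Ano8, Fam193b and Rab6b in Smart-seq, Pla2g6, Megf6, Ccdc85c, which had no read at 1 ng either, and Fbxl18 in DP-seq, and Ranbp2, Plxna1, Trrap and Tfdp1 in CEL-seq. Ranbp2, a nuclear pore gene, had 539 ± 1.96 CPM (SD, n = 2) in the standard control, and Megf6 81.0 ± 0.143 CPM. The transcription factor gene Foxo3 had 47.3 ± 0.858 CPM. Genes without reads were counted in libraries that were not thinned, and read totals differed. At 25 pg a library held 10239276 to 13531888 reads in Smart-seq, 4056243 to 8160912 in DP-seq and 2255515 to 11061474 in CEL-seq. The differences between methods in genes without reads are therefore mixed with read depth. The comparison with 1 ng was not made at equal depth either.

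At a common depth of 2255515 reads, standard RNA-seq detected 14191 genes. Smart-seq detected 13083 at 1 ng and 10547 at 25 pg, DP-seq 12642.0 and 9389, and CEL-seq 11641 and 7465. The median absolute log2 ratio between replicates was 0.116 in standard RNA-seq and rose from 0.241 to 0.635 in Smart-seq, from 0.194 to 0.842 in DP-seq and from 0.331 to 1.257 in CEL-seq. Spearman's rho of the levels with standard RNA-seq fell from 0.79 to 0.729, from 0.864 to 0.792 and from 0.752 to 0.626. Over 8 groups per method, each of the 9 relations to log10 input passed, although in Smart-seq that of noise did not with a minimum of 100 CPM (rho = -0.732, exact permutation p = 0.0548) nor that of the order of levels with a minimum of 10 CPM (rho = 0.586, exact permutation p = 0.153). For genes detected Pearson's r was 0.894, 0.912 and 0.926 (exact permutation p = 0.000794, 0.00198 and 0.000794) and Spearman's rho 0.927, 0.927 and 0.976 (exact permutation p = 0.00317, 0.00317 and 0.000794; adjusted 0.00408, 0.00408 and 0.00357). For replicate noise r was -0.852, -0.862 and -0.763 (exact permutation p = 0.00595, 0.0107 and 0.0365) and rho -0.878, -0.878 and -0.927 (exact permutation p = 0.0103, 0.0103 and 0.00317; adjusted 0.0103, 0.0103 and 0.00408). For the order of levels r was 0.943, 0.893 and 0.787 (exact permutation p = 0.000794, 0.00833 and 0.0226) and rho 0.927, 0.927 and 0.976 (exact permutation p = 0.00317, 0.00317 and 0.000794). Without the 1 ng groups r stayed at 0.837, 0.881 and 0.979 for genes detected, -0.792, -0.848 and -0.853 for noise and 0.87, 0.908 and 0.9 for the order of levels.

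Over the 8 matched groups, Smart-seq and DP-seq detected 2125.1 ± 776 and 1475.3 ± 735 more genes than CEL-seq (SD, n = 8; exact permutation p = 0.00781 and adjusted 0.0141 for both, higher in 8 of 8). The difference between Smart-seq and DP-seq, 650.0 ± 695 genes, did not pass (SD, n = 8, exact permutation p = 0.0625, adjusted 0.0703, higher in 5 of 8). Without thinning, where depth differs, it was 1232.1 ± 909 genes (SD, n = 8, exact permutation p = 0.0156, higher in 7 of 8). Noise was lower in Smart-seq and DP-seq than in CEL-seq, with differences of -0.237 ± 0.257 and -0.19 ± 0.171 (SD, n = 8; exact permutation p = 0.0156 and adjusted 0.0201 for both), and did not differ detectably between Smart-seq and DP-seq (-0.047 ± 0.109, exact permutation p = 0.289). The rho of levels was higher in DP-seq than in Smart-seq and CEL-seq and higher in Smart-seq than in CEL-seq (exact permutation p = 0.00781, adjusted 0.0141, in 8 of 8 groups each). Among genes with 10 CPM or more, the difference between Smart-seq and CEL-seq was -0.0063 (exact permutation p = 0.562).

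**Figure D3:**
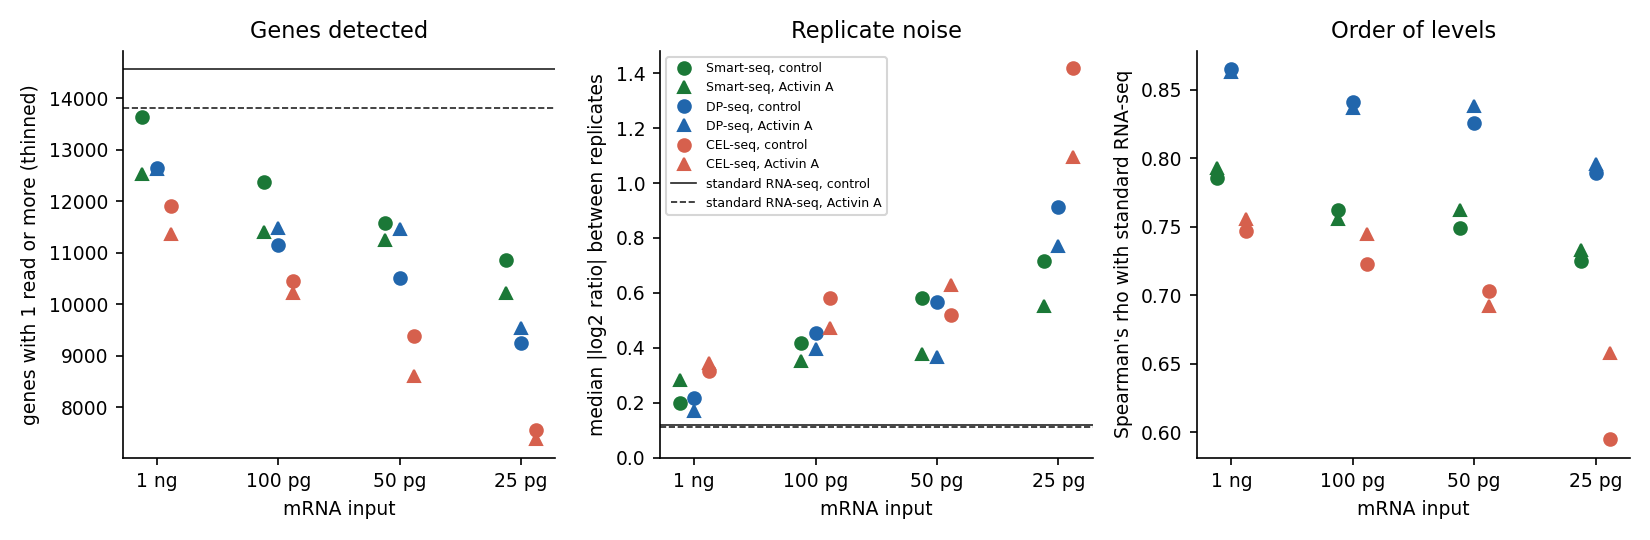
Genes with 1 read or more after thinning, median absolute log2 ratio between replicates and Spearman's rho of levels with standard RNA-seq (vertical axes) by mRNA input (horizontal axes); each point is a group of 2 libraries and lines are the standard groups. Noise rises to 1.257 in CEL-seq at 25 pg as the mean of both treatments, against 0.116 in standard RNA-seq.

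Genes with long transcripts had lower levels in Smart-seq than in standard RNA-seq. Across genes, Spearman's rho between transcript length and the log2 ratio to the standard level was -0.624 to -0.708 in the 8 Smart-seq groups and -0.137 to 0.053 in DP-seq. The levels are not normalised for length, and CEL-seq reads transcript ends only, so its relation to length follows in part from the assay and is not given.

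CEL-seq libraries held reads of genes that were near absent from the same condition in standard RNA-seq. In CEL-seq at 1 ng, Wnt1 had 47.6 CPM in control and 6.95 CPM with Activin A, where Smart-seq had 63.2 and 0 CPM and standard RNA-seq 124 and 0 CPM. En1 had 44.3 and 7.57 CPM in CEL-seq and 101 and 0.279 CPM in DP-seq. Among 43 genes at least 50-fold lower with Activin A in standard RNA-seq, the level with Activin A was a median 7.52% to 17.6% of the control level in CEL-seq, 0% to 0.768% in Smart-seq and 0.298% to 1.08% in DP-seq. Among 36 genes at least 50-fold higher, the control level was 7.88% to 23.0% of the Activin A level in CEL-seq, 0.105% to 1.92% in Smart-seq and 0.579% to 2.02% in DP-seq. In each input and direction, 21 to 34 of these genes had 10 CPM or more in the higher condition of the method and entered the median.

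**Figure D4:**
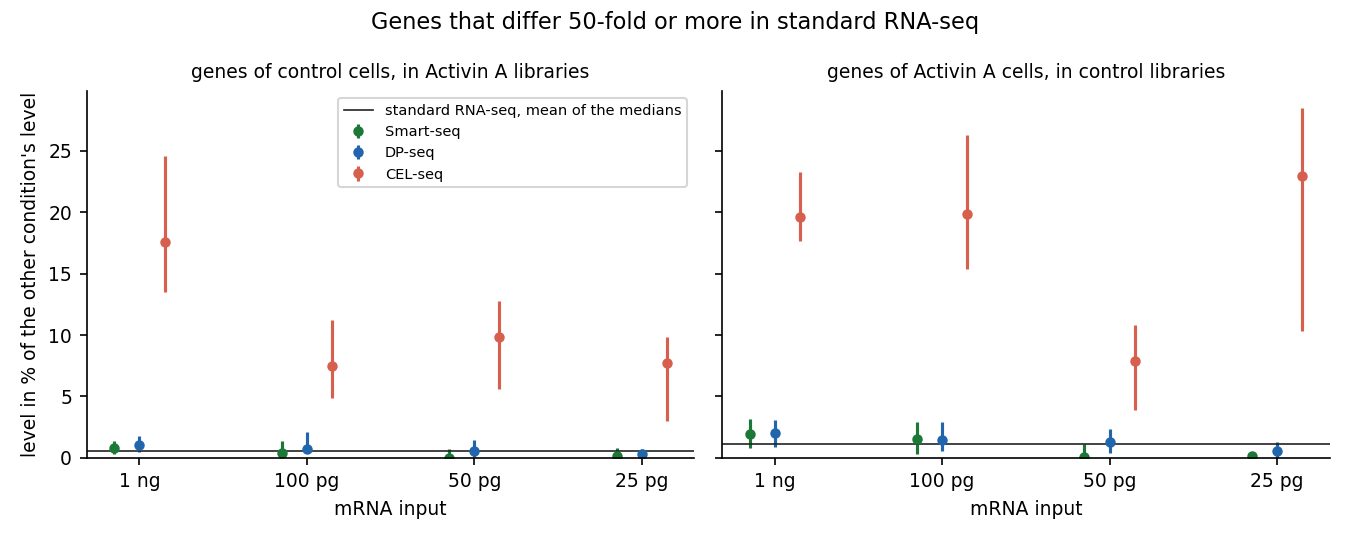
Level in the low condition as a percentage of the level in the high condition (vertical axis) by mRNA input (horizontal axis), for genes that differ 50-fold or more in standard RNA-seq; points are medians over genes, bars are quartiles and the line is the mean standard median. CEL-seq medians lie between 7.52% and 23.0%, Smart-seq and DP-seq medians at or below 2.02%.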

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

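The tests of read depth, of molecule sampling, of composition scaling and of carried-over reads against shrunken folds, and the minimum of 10 genes in the other test of carried-over reads, were chosen after the results they bear on had been seen; the other tests were set before. No biological explanation was tested for these patterns. The labels give the same 2 conditions for all methods, but whether standard RNA-seq used the same mRNA preparation is not given in the sources used here, and a different preparation stays open as untested.

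Responses at 1 ng that differ from standard RNA-seq by the test of the difference itself numbered 146 in Smart-seq, 901 in DP-seq and 63 in CEL-seq. The biological coefficient of variation fitted in these tests was 0.106, 0.0741 and 0.198, so their power differed. The counts therefore do not rank the methods by the size of the difference. The slope on the standard log2 fold changes at 1 ng was 0.874, 0.865 and 0.456, lowest in CEL-seq.

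DP-seq responses at 1 ng lay mostly below those of standard RNA-seq, in 739 of the 901 genes, and 26 of the 79 ribosomal protein genes tested were among them. Of 736 lower genes with both fold changes, 597 were higher with Activin A in standard RNA-seq, and the medians were 0.45 there and -0.11 in DP-seq. The called genes had a median level of 0.939 times that in standard RNA-seq, which met the bound set beforehand against few reads in DP-seq. Over all tested genes the median was 0.572 times. Genes with few reads are less readily called, so the level of the called genes cannot decide this explanation. Composition scaling stays open: with RLE size factors 68.8% of the calls were lower in place of 82%, between the bounds set for and against it. With the standard Activin A pair kept as 2 libraries 850 genes were lower and 734 higher, so the lower genes did not become fewer, but their share was 53.7% of 1584.

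Fewer genes were called at lower input in Smart-seq and DP-seq. Lower read depth is argued against, since with libraries thinned to the same total the calls at 1 ng were 30.5 times those at 25 pg in Smart-seq and 74.7 times in DP-seq. Smaller measured folds are argued against as well, since the slope on the standard fold changes at 25 pg was at least 1.06 times that at 1 ng in each method. Loss of reads on one side can enlarge a measured fold, so the slope does not show that true folds were kept. For example, T had 0 CPM in the Smart-seq control at 25 pg and a log2 fold change of 13.21, against 5.21 at 1 ng. Sampling of few mRNA molecules may contribute and stays open: the squared coefficient of variation beyond read sampling at 100 to 1000 CPM changed with input with log10 slopes of -0.54 ± 0.18 (SE, n = 8) in Smart-seq, -0.93 ± 0.14 in DP-seq and -0.87 ± 0.21 in CEL-seq, where sampling alone gives a slope near -1, and -1.0, -1.17 and -1.98 without 1 ng. With a spread shared over inputs the calls rose toward 25 pg (543 to 2189 in Smart-seq), so the order of the counts depends on the fit. The shared biological coefficient of variation was 0.653 in Smart-seq and 0.685 in DP-seq. Separate fits gave 0.139 and 0.105 at 1 ng and 0.837 and 0.936 at 25 pg. The shared spread was thus larger than that measured at 1 ng and smaller than that at 25 pg. The shared fit also changed the genes tested and the scaling, and these changes were not separated from that of the spread.

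CEL-seq libraries held 7.52% to 23.0% of the other condition's level for genes that differ more than 50-fold in standard RNA-seq. A candidate explanation is reads carried over between CEL-seq libraries: genes changed 4 to 16-fold lay nearer to a mixture of both conditions than to folds shrunk by a common factor in 8 of 8 combinations of input and direction. The 8 of 8 is weaker than it looks, because for genes lower with Activin A the observed ratios at 50 and 25 pg, 0.146 and 0.085, lay below the mixture (0.247 and 0.234), the shrunken folds (0.444 and 0.405) and standard RNA-seq (0.157 and 0.165). A second test used genes with 0 reads in one standard condition, but at most 3 genes (Hes3, Wnt1 and Pax5) met the level, and a minimum of 10 genes was set after that was seen, so this test leaves the explanation open. In those few genes the median share was 3.74% to 20.7% in CEL-seq, above the 0.5% set beforehand for carried-over reads. The share was 0% to 0.0775% in Smart-seq, under the bound set beforehand against carried-over reads, and 0% to 0.492% in DP-seq.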

How the results depend on the processing

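The alternatives were fixed before the data were examined, except keeping the standard Activin A pair as 2 libraries and testing transcripts without summing, which were chosen after. Among counts of calls under an alternative, 126 stayed within 1.5 times the reported count and 85 moved. Among values of named genes, 867 kept direction and threshold, 10 kept the direction only and none reversed; Bmp4, Kdr and Tfcp2l1 in standard RNA-seq missed the threshold with DESeq2 and with thinned libraries, Cfap206 with DESeq2 and Phlda3 with thinned libraries. Of the gene list tests, 45 kept a call, 17 lost it, 1 gained it and 89 were not called under either setting. Where the cause of a change is not named, the cause was not tested.

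With DESeq2 the calls were 2237 and 1317 in Smart-seq at 50 and 25 pg, 1784 and 758 in DP-seq at 50 and 25 pg, and 690, 1123, 2162 and 420 in CEL-seq from 1 ng to 25 pg, with 1853 in CEL-seq over all inputs. DESeq2 called 343 genes for the CEL-seq difference from standard RNA-seq, and 531 and 736 for 25 pg against 1 ng in Smart-seq and DP-seq. Recovery of the standard calls with DESeq2 was 1657 and 1039 in Smart-seq and 1407 and 565 in DP-seq at 50 and 25 pg, and 595, 745, 1117 and 185 in CEL-seq. RLE scaling gave 84 genes for the Smart-seq difference, and 1 and 2 for 25 pg against 1 ng in Smart-seq and DP-seq.

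Without a filter on low counts the calls were 1032 and 148 in Smart-seq at 100 and 25 pg, 1311 and 307 in DP-seq at 50 and 25 pg, 1522, 715, 657 and 9 in CEL-seq, 1308 in CEL-seq over all inputs, and 30, 361 and 12 for the differences of Smart-seq, DP-seq and CEL-seq from standard RNA-seq. A fit per method that shares the spread over inputs gave 543, 1048, 1863 and 2189 in Smart-seq, and 302, 393 and 1796 in DP-seq at 1 ng, 100 pg and 25 pg. It gave 0 in CEL-seq at 1 ng and 0 at 25 pg by edgeR, where 210 and 2698 of 10755 tested genes had an unadjusted p under 0.05. DESeq2 on these separate CEL-seq inputs called 690 and 420. The pair kept as 2 libraries gave 951, 1584 and 469 differences. CEL-seq over all inputs without 25 pg gave 1546. Libraries thinned to the lowest total, which holds fewer reads, gave 5464 standard and 2990 Smart-seq calls at 1 ng and recovery of 2302 in Smart-seq and 3046 in DP-seq at 1 ng. A fold of 2 or more, a stricter threshold, left 4360 standard calls, 3363 in Smart-seq and 2766 in DP-seq at 1 ng. Recovery was then 2512, 981 and 348 in Smart-seq from 1 ng to 50 pg, 2265 in DP-seq at 1 ng and 17 in CEL-seq at 25 pg. As shares of the standard calls under the same setting, recovery at 1 ng was 57.6% in Smart-seq and 51.9% in DP-seq with this threshold. It was 42.1% and 55.7% with thinned libraries, against 43.7% and 48.2% in the main fits.

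Leaving out 1 library, where the lone library of a group is assumed to vary like the other group, gave ranges of 280 to 1067 (Smart-seq 100 pg), 10 to 1924 (50 pg) and 0 to 57 (25 pg, where edgeR gave 0 without either Activin A library at 1052 and 1070 genes with an unadjusted p under 0.05); 3581 to 6064 (DP-seq 1 ng), 772 to 1660 (100 pg), 222 to 2236 (50 pg) and 74 to 179 (25 pg); and 0 to 1417 (CEL-seq 1 ng), 0 to 951 (100 pg), 0 to 2952 (50 pg) and 0 to 87 (25 pg). In the CEL-seq fits by edgeR that gave 0, 931, 1339, 2736 and 59 genes from 1 ng to 25 pg had an unadjusted p under 0.05. In standard RNA-seq, leaving out a control library leaves no residual degree of freedom once the Activin A pair counts as 1, so no test was made there.

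The replicate numbers did not meet the rule for pairing samples, a correlation over 0.1 in every pair: the correlation of same-numbered deviations was 0.309 in Smart-seq at 1 ng, 0.132 and 0.164 in CEL-seq at 100 and 50 pg, and -0.025 to 0.07 elsewhere. In CEL-seq, replicate 2 had more genes detected after thinning in 8 of 8 groups, a hint from the data that the numbers mark a shared step there. With the replicate block the calls were 1275 in DP-seq at 50 pg, 1 and 0 in CEL-seq at 1 ng and 25 pg by edgeR (2289 of 9426 and 147 of 6217 tested genes with an unadjusted p under 0.05), and 242 in CEL-seq over all inputs. Fits with standard RNA-seq also kept the Activin A pair as 2 libraries, which a block needs: the Smart-seq, DP-seq and CEL-seq differences were then 1550, 1295 and 53, against 951, 1584 and 469 with the pair alone kept as 2, and the naive pluripotency list passed in standard RNA-seq (adjusted p = 0.046), where the effects of both changes were not separated.

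With an estimated inter-gene correlation, 17 list calls were lost: in standard RNA-seq the adjusted p was 0.697 for primitive streak, Nodal pathway, neuroectoderm, cholesterol synthesis, glycolysis and ribosomal proteins and 0.739 for definitive endoderm. In Smart-seq it was 0.294 for ribosomal proteins, in DP-seq 0.0557 for trophoblast and for cholesterol synthesis and 0.176 for ribosomal proteins, and in CEL-seq 0.09 for primitive streak, definitive endoderm and glycolysis, 0.134 for the Nodal pathway, 0.112 for neuroectoderm and 0.235 for ribosomal proteins.

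Pearson's r of fold changes with a minimum of 1 CPM was 0.888, 0.759, 0.699 and 0.648 in Smart-seq, 0.898, 0.746 and 0.689 in DP-seq from 1 ng to 50 pg and 0.707 in CEL-seq at 1 ng. With a minimum of 100 CPM it was 0.877, 0.794 and 0.738 in Smart-seq and 0.892, 0.833 and 0.73 in DP-seq from 100 to 25 pg, and 0.778, 0.616 and 0.459 in CEL-seq from 1 ng to 50 pg. With a minimum of 10 CPM the relation of level agreement to input in Smart-seq was rho = 0.586 (exact permutation p = 0.153), and the difference between Smart-seq and CEL-seq reversed to -0.0063. The relation of noise to input in Smart-seq was rho = -0.732 with a minimum of 100 CPM (exact permutation p = 0.0548). Without thinning, Smart-seq detected 1232.1 more genes than DP-seq (exact permutation p = 0.0156), which passes.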

Other observations

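The split counts below were planned before the results were seen, and the other values are descriptions that carry no explanation.

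Signalling targets moved apart within their lists in standard RNA-seq. Of 11 Wnt target genes, 7 fell and 4 rose (camera adjusted p = 0.286): Axin2, a negative feedback gene of the pathway, had a log2 fold change of -1.95 ± 0.05 (SE) and the transcription factor gene Sp8 -3.11 ± 0.09, whereas Tcf7 and the secreted antagonist Dkk1 changed by 1.32 ± 0.04 and 2.10 ± 0.10. Axin2 also fell in Smart-seq (-1.94 ± 0.26), DP-seq (-2.06 ± 0.18) and CEL-seq (-1.73 ± 0.42) over all inputs. Of 9 BMP target genes, 4 rose and 3 fell (adjusted p = 0.684), with Id1 at 2.87 ± 0.13, Bambi at 1.74 ± 0.14 and Id3 at -0.62 ± 0.07. Of 10 p53 target genes, 4 rose and 4 fell (adjusted p = 0.684), with Perp, which encodes a junction protein, at 3.69 ± 0.15 and Zmat3 at -1.13 ± 0.04. Of 12 mitosis genes, 6 rose and 3 fell (adjusted p = 0.676), with Ccnb2 at 0.69 ± 0.05 and Mki67 at -0.77 ± 0.02.

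In the amplified methods none of these 4 lists passed camera. The smallest adjusted p were 0.196 for Wnt targets and 0.5 for p53 targets in Smart-seq, 0.804 for mitosis in DP-seq and 0.578 for BMP targets in CEL-seq. The other lists that had not passed in standard RNA-seq gave, for Smart-seq, DP-seq and CEL-seq in turn, adjusted p = 0.5, 0.152 and 0.578 for haematovascular genes, 0.557, 0.774 and 0.769 for paraxial mesoderm, 0.262, 0.532 and 0.249 for epithelial to mesenchymal transition, 0.549, 0.774 and 0.578 for extraembryonic endoderm and 0.608, 0.774 and 0.265 for fibroblast genes. Called members numbered 8 of 12, 8 of 12 and 4 of 12 for epithelial to mesenchymal transition and 0 of 9, 0 of 6 and 2 of 5 for fibroblast genes by edgeR. Trophoblast genes gave adjusted p = 0.137 in Smart-seq and 0.119 in CEL-seq, and naive pluripotency genes 0.684 and 0.609. Among lists not passing, the median, the mean and the test differed in sign for naive pluripotency and mitosis in Smart-seq, for paraxial mesoderm, BMP targets, epithelial to mesenchymal transition, extraembryonic endoderm and fibroblast genes in DP-seq, and for paraxial mesoderm and BMP targets in CEL-seq.

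Some genes were called over all inputs of a method but not in standard RNA-seq, where they had 10 CPM or more. Sec61b, a subunit of the protein translocation channel, changed by -0.08 ± 0.07 in standard RNA-seq but by 0.66 ± 0.08 in Smart-seq (adjusted p = 2.91e-05), 0.60 ± 0.10 in DP-seq (adjusted p = 0.000333) and 0.94 ± 0.23 in CEL-seq (adjusted p = 0.0241). Rpl15 changed by -0.04 ± 0.02 in standard RNA-seq and by 0.45 ± 0.05, 0.46 ± 0.11 and 0.77 ± 0.18 in the 3 methods (adjusted p = 6.11e-06, 0.00539 and 0.0215). Malat1 was called in opposite directions, with a log2 fold change of -0.94 ± 0.03 in standard RNA-seq, 1.09 ± 0.30 in Smart-seq (adjusted p = 0.0117) and 1.27 ± 0.22 in DP-seq (adjusted p = 0.000505), and was not called in CEL-seq (-0.02 ± 0.35, adjusted p = 0.977). The differences over all inputs were not tested against standard RNA-seq. Other genes called over all inputs of a method but not in standard RNA-seq were Eif1b and Cfl1 in Smart-seq, Dek, Ppig and Hnrnpa2b1 in DP-seq, and Ran, Oxsm, Sart1 and Tmem198b in CEL-seq; the Oxsm and Tmem198b calls were lost with the replicate block (adjusted p = 0.0509 and 0.0935).

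For each method, 100 splits of its 16 libraries that keep 2 libraries of each input on either side were drawn, the real split included. Only 1 of the 100, the real split, gave as many genes as the 4384 of Smart-seq, the highest other split giving 1234. For DP-seq it was also 1 of the 100, with 2628 genes against a highest other of 0 by edgeR, and for CEL-seq 1 of the 100, with 719 against 38. The libraries are technical replicates, so any difference between the control and Activin A cultures would place the real split first. The splits therefore cannot tell an effect of Activin A from a chance difference between cultures. The highest other values depend on which splits were drawn. The other splits with 1234 and 38 genes parted 3 of the 4 inputs exactly by treatment.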
